A study of Mus musculus with 4 samples.

How the data were processed

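Total RNA from cultured mouse telencephalic neuroepithelial cells was measured on 4 Affymetrix arrays, 2 for E11.5 cells cultured 1 day and 2 for E14.5 cells cultured 4 days. Per the labels, 5 µg of RNA was copied into cDNA with an oligo-dT primer carrying a T7 promoter, transcribed into biotin-labelled cRNA and hybridised. The deposited values are 1 linear intensity per probe set and array, a probe set being a group of short probes for 1 transcript. They were made with GCOS, the array manufacturer's software, per the submitters' processing notes; its version and settings are not given in the sources used here, and detection calls were not used here. The groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures or animals. The p-values of single probe sets therefore measure only the spread between these arrays, which may be technical.

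The table held 45101 probe sets, of which 64 were control probe sets and were set aside. Of the other 45037, the platform annotation named 1 gene for 34945, several genes for 932 and none for 9160; only probe sets with 1 gene were named. Symbols were looked up through Entrez identifiers in a table of mouse genes, which left 204 single-gene probe sets unmatched, under the symbol of the annotation, and updated 0 symbols. No genome build is named in the files, so no positions are given.

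The 2% trimmed means of the arrays differed by up to 2.43-fold, beyond the 5% set beforehand as the limit for leaving values as deposited. Each array was therefore multiplied by 1 factor (0.932 and 0.691 for the E11.5 arrays, 1.13 and 1.68 for the E14.5 arrays) to a common trimmed mean of 174. Probe sets with a mean scaled signal at or above the 40th percentile (27.3) were kept, which left 27022. A pseudocount of 12.8, the 25th percentile of all scaled values, was added before taking log2. The pseudocount shrinks differences of genes with a signal near or below it in 1 group, so their log2 differences are smaller than the ratios of their mean signals. The ratio of 3' to 5' probe sets ran from 0.806 to 0.879 for Gapdh and from 1.10 to 1.14 for beta-actin over the 4 arrays.

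Differences were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with a trend of variance on signal, as E14.5 minus E11.5, with 2 residual and 7.99 prior degrees of freedom. Benjamini-Hochberg adjustment covered all 27022 probe sets and the threshold was an adjusted p of 0.05. Adjusted p-values in the text are from this fit unless camera is named or a list is meant. A gene was represented by its tested probe set with the highest mean signal, which gave 12952 genes. Genes with a called representative and another probe set called in the opposite direction were counted. Values in parentheses after a gene are log2 differences ± SE, and mean signals are scaled values averaged over the 2 arrays of a group.

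There were 28 gene lists, drawn from textbook knowledge. They cover astrocyte markers, gliogenic regulators, oligodendrocyte lineage, neuronal markers, ventral telencephalon and GABAergic lineage, proneural factors and intermediate progenitors, early progenitor identity, and neural progenitor and radial glia markers. Pathway lists are JAK-STAT, BMP-SMAD, Notch, Wnt, and FGF and ERK. Others are proliferation and mitosis, DNA replication, DNA methylation and chromatin repression, cholesterol synthesis, interferon response and MHC class I, imprinted genes, extracellular matrix and adhesion, stress and immediate early genes, hypoxia and glycolysis, and sex-linked transcripts. Cells of other types are covered by endothelial and pericyte, microglia and macrophage, meningeal and mesenchymal, erythroid, and choroid plexus and ependymal markers. Lists with at least 5 measured members were tested two-sided with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 such lists. At a preset correlation, camera compares the members of a list with all other genes. Its p-values then treat genes, not arrays, as the replicates and do not measure the spread between arrays. For each list, members past the threshold were counted over all probe sets and adjusted over the list alone.

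The lists, the tests, the scaling rule, the filter, the alternatives and the rule for naming genes were fixed before the data were examined. That rule takes the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, passing over unnamed, clone and predicted symbols. It also takes up to 4 called members of each list by size of difference, up to 4 members that did not pass, by signal, for astrocyte markers, gliogenic regulators and early progenitor identity, and Gfap and S100b. It names 126 genes. The genes named outside the rule were chosen after their values were seen: the exceptions to the direction of a list (Hopx, Lhx2, Gsx1, Igf2bp3, Jag1, Gnas, Impact, Irf1), the members that did not pass in short lists (Mbp, Mag, Map2, Ncam1), Fn1, Lama1, Vcan, Col3a1, Pcx, Tfrc, Lyz2, Cx3cr1, Spi1 and Trem2, and the genes with probe sets in disagreement.

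The alternatives were quantile normalization or median scaling between arrays, a pseudocount of an eighth of the value used or at the median of all values, no filter or one at the 60th percentile, and no variance trend. Others left out probe sets that can match several transcripts, averaged the probe sets of a gene, estimated the correlation in camera from the residuals, used the replicate number as a block, and left out each array in turn. With 1 array left in a group, that array is assumed to vary like the other group. The fit was tested on simulated data, with 20 draws of 200 changed probe sets among 27022: it recovered 18.2% of 2-fold and 62.5% of 4-fold changes, and 6.28% of its calls were false. A shifted list was called in 5 of 5 draws, and 0 of 123 tests of unchanged lists were called. These rates hold for that simulation. In the comparison itself 6408 probe sets were called, which makes the threshold on unadjusted p-values less strict, so the rates do not carry over to it. The recovery at which the simulation counts as passed was lowered after its first draws were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.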

Results

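Gene expression was measured on 4 arrays of neuroepithelial cells from the telencephalon of ICR mouse embryos. Neuroepithelial cells are the dividing precursors from which the neurons, astrocytes and oligodendrocytes of the forebrain arise. In 1 group of 2 arrays, the cells came from embryos at embryonic day 11.5 (E11.5) and had been cultured for 1 day. The other group of 2 arrays held cells from embryonic day 14.5 (E14.5), cultured for 4 days. Both cultures contained 10 ng/ml basic FGF, a growth factor that keeps such precursors dividing, on dishes coated with polyornithine and fibronectin. The 2% trimmed mean intensity was 187 and 252 on the E11.5 arrays and 154 and 103 on the E14.5 arrays. After scaling to 1 common trimmed mean, log2 signals correlated across probe sets at r = 0.975 between the E11.5 arrays and r = 0.969 between the E14.5 arrays. Between the groups r lay from 0.885 to 0.909; these are correlations across probe sets, which are not independent replicates. A 2-fold difference separated the E11.5 arrays at 663 of 27022 probe sets and the E14.5 arrays at 1074. Between arrays of different groups the number was 3453 to 4393. The number of arrays, 2 per group, limits the precision of every value.

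The comparison of E14.5 with E11.5 cells shows which transcripts differed. Which genes hold back astrocyte formation in precursors of midgestation was not tested. A constant of 12.8, the pseudocount, was added to every scaled signal before log2 was taken. Of the 12 largest rises 5 genes, and of the 12 largest falls 7, had a mean below it in 1 group, so the size and order of their differences depend on it. Gpr17, a receptor of immature oligodendrocytes, rose to a mean scaled signal of 1967 at E14.5 from a mean below the pseudocount at E11.5. Its log2 difference, E14.5 minus E11.5, was 7.05 ± 0.20 (SE, n = 2 arrays per group, as for all differences given with an SE). It ran from 5.50 to 9.10 with larger and smaller pseudocounts. Prkcq (5.63 ± 0.23), Omg (5.45 ± 0.21), Ramp1 (5.05 ± 0.21) and Matn4 also rose from below the pseudocount. The other rises, with means above it in both groups, were those of Pdgfra (5.21 ± 0.14), Lyz1, Ppp1r3c, Rlbp1, Egfr, Cbr3 and Pla2g7. The probe set of Lyz1 can also detect its close relative Lyz2, so its identity is uncertain. Averaged over its probe sets, the difference of Egfr was 2.67. Fgf15, an FGF ligand of the early forebrain, fell from a mean of 628 to below the pseudocount (-5.36 ± 0.25, and -7.27 to -3.89 with smaller and larger pseudocounts). The transcription factors Isl1 (-5.07 ± 0.23) and Lhx8 (-4.85 ± 0.33), the embryonic globin Hbb-y (-4.42 ± 0.45), Rspo2, Mab21l1 and St18 (-2.55 with its probe sets averaged) also fell to below it. The other falls, with means above it in both groups, were those of Islr2 (-5.17 ± 0.32), Stmn2, Tmem130, Tbr1 and Stmn4. With the pseudocount at an eighth, 7 of the 12 rises and 8 of the 12 falls were still among the 12 largest. With the median of all values as pseudocount, 9 of the rises and 9 of the falls were. The genes that dropped out at an eighth were Ppp1r3c, Rlbp1, Egfr, Cbr3, Pla2g7, Stmn2, Tmem130, Tbr1 and Stmn4. All of these had means above 12.8 in both groups, so the order depends on the pseudocount for such genes too. All 24 genes had adjusted p-values of 0.00010 or less in the limma fit, and their groups did not overlap. Among the other genes named by rule, Crabp2, Fezf1, Neurog1, Cspg4, Wnt8b, Plvap, C1qa, C1qc, Hba-x and S100b had a group mean below the pseudocount, which makes 22 of 126, and the sizes of their differences depend on it too.

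Of 12952 genes tested, 1850 were higher and 1756 lower at E14.5, together 27.8%. At least a 2-fold change was reached by 838 of the genes that were higher and 812 of those that were lower. Over all 27022 probe sets, 3012 were higher and 3396 lower, of which 1400 and 1612 changed at least 2-fold. For 7 genes the representative probe set was called and another probe set was called in the opposite direction. These were Camk2a, Ppp2r5c, Rpl41, Tlk1, Tln1, Tpm3 and Trio. Without the trend of variance on signal, 1919 probe sets were higher and 2097 lower, and 1150 and 1101 genes. Each direction is relative to the average signal of an array, since every array was scaled to the same trimmed mean.

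Astrocyte markers rose as a group. Of 23 measured members 19 were higher at E14.5, none was lower and 4 did not pass the test; adjusted over the list alone, 20 were higher and 1 lower. Gfap, the intermediate filament of astrocytes, rose from a mean scaled signal of 22.2 to 113 (log2 difference 1.77 ± 0.34, adjusted p = 0.0039). Apoe, a lipid carrier secreted by astrocytes, rose from 218 to 4886 (4.37 ± 0.23). The water channel Aqp4 rose by 3.96 ± 0.21, the sodium pump subunit Atp1b2 by 3.65 ± 0.18 and the protease inhibitor Timp3 by 3.63 ± 0.24 (2.04 with its probe sets averaged). S100b, a calcium-binding protein of astrocytes, rose from 11.1 to 49.4 (1.42 ± 0.42, adjusted p = 0.035). The call of S100b was lost without E11.5 replicate 2, where the difference was 0.99, and without E14.5 replicate 1, where it was 1.19, as well as without a filter and with a smaller pseudocount. The gap junction gene Gja1 had a mean of 1573 at E11.5 and 1060 at E14.5 and did not pass the test at its brightest probe set (-0.60 ± 0.24, adjusted p = 0.10). It passed, as lower, without E11.5 replicate 2 (-0.83), without E14.5 replicate 1 (-0.99) and with its probe sets averaged. Other members that did not pass were Cd44 (0.59 ± 0.23), Clu (0.19 ± 0.33) and Slc7a10 (-0.09 ± 0.41). Cd44 passed without E11.5 replicate 1 (0.62) or E14.5 replicate 2 (0.97). Clu passed without E14.5 replicate 2 (0.77), while its sign turned without E11.5 replicate 1 (-0.10) and without E14.5 replicate 1 (-0.39), and that of Slc7a10 without E11.5 replicate 1 (0.43) and without E14.5 replicate 2 (0.32). The median difference of the list was 2.02, and camera with a preset correlation gave an adjusted p of 1.7e-13. That p-value, like those of the other lists, treats genes rather than arrays as the replicates. The same test gave adjusted p = 0.25 with an estimated correlation.

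**Figure D1:**
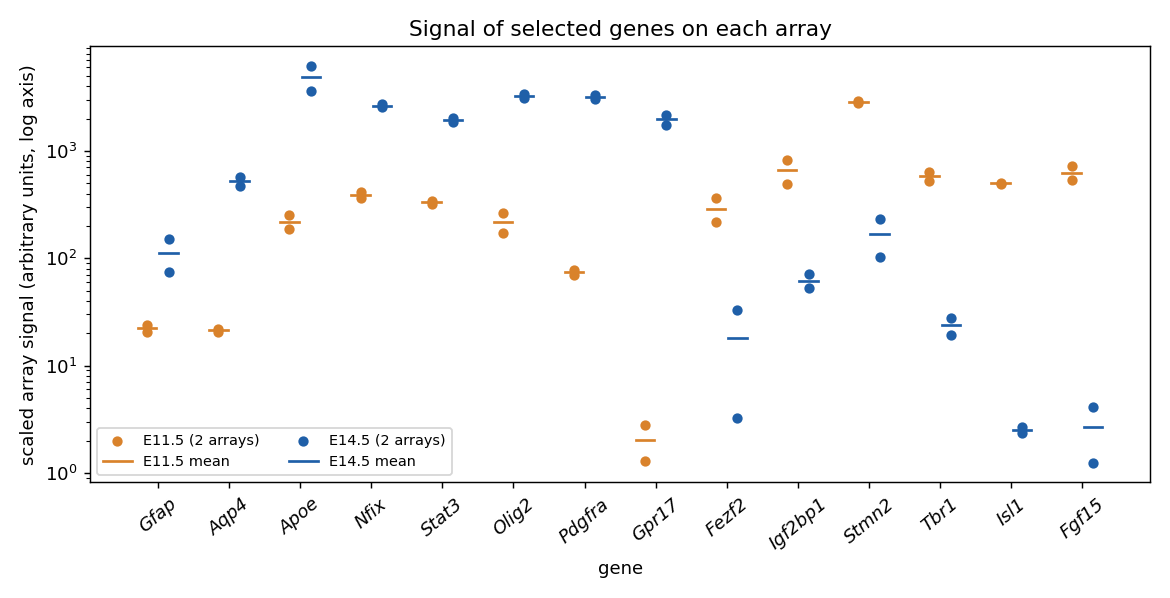
Scaled array signal (arbitrary units, log axis) of 14 genes on each of the 4 arrays, with E11.5 in orange and E14.5 in blue; points are single arrays and horizontal bars are group means. Gfap rises from a mean of 22.2 to 113 and Gpr17 from 2.03 to 1967, while Stmn2 falls from 2851 to 166 and Fgf15 from 628 to 2.68.

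Regulators of gliogenesis moved in both directions, with more members higher than lower. Of 16 measured genes 9 were higher, 3 were lower and 4 did not pass the test (adjusted over the list alone, 10 higher and 3 lower). Olig2, a transcription factor of the oligodendrocyte lineage, rose from a mean of 219 to 3243 (3.84 ± 0.18). Sox8 rose by 2.87 ± 0.19 and Nfix, a nuclear factor I protein that activates glial genes, by 2.73 ± 0.13. The members that fell were Id4 (-1.77 ± 0.16), Hopx (-1.68 ± 0.14) and Lhx2 (-0.74 ± 0.12); the homeobox factor Lhx2 is known to favour neuron over astrocyte formation. Etv5 (0.32 ± 0.15), Id3 (0.44 ± 0.18), Id2 (0.20 ± 0.14) and Pou3f2 (mean signals 90.4 and 91.4) did not pass the test. Id3 passed without E11.5 replicate 1 (0.72). The sign of Pou3f2 turned under quantile normalization (0.057), with a larger pseudocount, and without E11.5 replicate 2 (0.14) or E14.5 replicate 1 (0.24). The list had a median of 0.75 and a camera adjusted p of 0.0067, against adjusted p = 0.25 with an estimated correlation.

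Genes of the oligodendrocyte lineage gave the largest rise of any list tested. Of 15 measured members 13 were higher and none was lower, over all probe sets and adjusted over the list alone. After Gpr17 and Pdgfra, the receptor that marks oligodendrocyte precursors (73.9 to 3204), came Bcas1 (4.42 ± 0.20; 2.19 with its probe sets averaged) and the proteoglycan Cspg4 (4.37 ± 0.26). The myelin genes Mbp (-0.42 ± 0.19) and Mag (-0.28 ± 0.34) did not pass the test. Olig2 and Sox8 belong to both this list and the gliogenic regulators. The median was 3.51 and the camera adjusted p 6.4e-13, with adjusted p = 0.25 with an estimated correlation.

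Markers of cells from outside the neural lineage also differed between the groups. Microglia and macrophage markers were higher at E14.5 for 12 of 15 measured members, with none lower (13 and none when adjusted over the list alone). The complement genes C1qa (6.17 to 229; 3.68 ± 0.27), C1qc (3.08 ± 0.35) and C1qb (2.76 ± 0.36) and the signalling adaptor Tyrobp (3.10 ± 0.22) were among those that rose. This list rose together with the astrocyte and oligodendrocyte lists, with a median of 2.20 and a camera adjusted p of 1.9e-08, against adjusted p = 0.25 with an estimated correlation. Erythroid genes had only 4 measured members, too few for the list test. Of these, Hbb-y (511 to 12.3) and Hba-x (51.4 to 8.87; -1.64 ± 0.46) fell and 2 did not pass, with the same counts adjusted over the list alone. The call of Hba-x was lost without E11.5 replicate 1 (-1.34), without E14.5 replicate 1 (-1.10), without a filter, without the variance trend and with a smaller pseudocount.

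Among endothelial and pericyte markers 6 of 18 were measured, and of these Plvap (2.23 ± 0.36) and Ramp2 (1.10 ± 0.25) were higher and Egfl7 (-1.26 ± 0.34) was lower, as also adjusted over the list alone. Ramp2 lost its call without E14.5 replicate 2 (0.81), and Egfl7 lost its call without E11.5 replicate 1 (-0.96), without E14.5 replicate 2 (-0.85), without a filter, without the variance trend and with probe sets averaged (-0.44). The list did not shift (camera adjusted p = 0.91), and its median of -0.19 had the opposite sign to its mean of 0.18 and to the test. Meningeal and mesenchymal markers did not shift either (adjusted p = 0.68). Of 14 members 2 were higher and 3 lower (2 and 4 adjusted over the list alone). Pdgfra, which this list shares with the oligodendrocyte lineage, and Thy1 (2.52 ± 0.32) rose, while the collagen-binding Lum (-1.78 ± 0.24) and the collagens Col1a2 (-1.15 ± 0.22) and Col3a1 (-0.83 ± 0.17) fell. Its median was -0.15 and its mean 0.20. Choroid plexus and ependymal markers had 1 of 9 members lower, Otx2 (-2.06 ± 0.21), and none higher, also adjusted over the list alone (median -0.15, adjusted p = 0.59).

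Neuronal genes fell. Of 22 measured neuronal markers 20 were lower at E14.5, none was higher and 2 did not pass the test, with the same counts adjusted over the list alone. Stmn2, a regulator of microtubules in growing neurites, fell from a mean of 2851 to 166 (-4.10 ± 0.28). Tbr1, a transcription factor of early cortical neurons, fell from 583 to 23.7 (-4.03 ± 0.22), the neuronal tubulin Tubb3 from 2045 to 172 (-3.57 ± 0.27) and the secreted protein Reln from 1484 to 141 (-3.29 ± 0.18). The members that did not pass were Map2 (0.22 ± 0.12) and Ncam1 (-0.22 ± 0.13). The median was -2.11 and the camera adjusted p 1.7e-16, with adjusted p = 0.25 with an estimated correlation. Averaged over the 2 groups, these genes had a median difference of -0.22 on the dimmer array from the brighter array. The E14.5 arrays were the dimmer group.

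The ventral telencephalon and GABAergic lineage list fell as well, with 14 of 18 measured members lower and 1 higher, also adjusted over the list alone. Isl1 (501 to 2.52) and Lhx8 (624 to 11.1), both transcription factors of ventral neurons, led this list. They were followed by the vesicular GABA transporter Slc32a1 (-3.35 ± 0.39) and Dlx5 (-3.00 ± 0.21). Gsx1, a homeobox factor of ventral progenitors, was the member that rose (1.86 ± 0.31). The median was -1.95 and the camera adjusted p 3.2e-09, with adjusted p = 0.25 with an estimated correlation.

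Proneural factors and genes of intermediate progenitors were lower for 8 of 16 members and higher for 4 (10 and 4 adjusted over the list alone). Eomes, a marker of cortical intermediate progenitors, fell from 409 to 24.5 (-3.50 ± 0.21), the proneural factor Neurog1 by 2.35 on the log2 scale (-3.89 to -1.30 with smaller and larger pseudocounts) and Cbfa2t3 by 2.25. The Notch ligand Dll3 rose by 1.94 ± 0.12. The list median was -0.88 and the camera adjusted p 0.016, with adjusted p = 0.33 with an estimated correlation.

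Genes of early progenitor identity were lower for 10 of 16 measured members and higher for 1 (11 and 2 adjusted over the list alone). The retinoic acid binding protein Crabp2 fell from a mean of 248 to 10.3 (-3.58 ± 0.34). The forebrain transcription factors Fezf2 (-3.44 ± 0.44) and Fezf1 (-3.20 ± 0.30) fell, as did the RNA-binding protein Igf2bp1 (-3.15 ± 0.25), which went from 663 to 61.6. The member that rose was Igf2bp3, a relative of Igf2bp1 (0.54 ± 0.15). Nr2f1, a nuclear receptor also named COUP-TFI, had means of 1274 and 1393 and did not pass the test (0.12 ± 0.14, adjusted p = 0.59). Dmrta1 (0.60 ± 0.22), Crabp1 (-0.73 ± 0.31) and Prtg (-0.40 ± 0.39) did not pass either. Without E14.5 replicate 1, Dmrta1 (0.88) and Crabp1 (-1.20) passed, and Dmrta1 also passed with probe sets averaged. The sign of Nr2f1 turned without E14.5 replicate 1 (-0.024), and that of Prtg without E11.5 replicate 1 (0.026) or E14.5 replicate 1 (0.031). The median of the list was -0.99 and the camera adjusted p 5.5e-05, with adjusted p = 0.25 with an estimated correlation.

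Markers of neural progenitors and radial glia divided between rises and falls. Of 22 members 7 were higher and 8 lower (8 and 9 adjusted over the list alone). The matrix protein Tnc rose from 179 to 1294 (2.76 ± 0.15) and the Notch target Hes5 from 793 to 2775 (1.81 ± 0.17). Gli3, a transcription factor of the hedgehog pathway, fell from 1296 to 234 (-2.40 ± 0.15), and Id4 fell from 2790 to 814. The list did not shift (median -0.26, adjusted p = 0.59).

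Genes of DNA replication were lower at E14.5 for 22 of 25 measured members (23 adjusted over the list alone), and none was higher. The licensing factors Cdc6 (274 to 51.0; -2.17 ± 0.20) and Cdt1 (-1.37 ± 0.17), the chromatin assembly subunit Chaf1b (-1.54 ± 0.16; -0.88 with its probe sets averaged) and the ribonucleotide reductase subunit Rrm2 (-1.31 ± 0.17) fell most. The median was -0.95 and the camera adjusted p 6.1e-12, with adjusted p = 0.29 with an estimated correlation. Genes of proliferation and mitosis had 11 of 23 members lower and none higher (17 and none adjusted over the list alone). The mitotic kinases Bub1 (-1.02 ± 0.15), Ttk (-0.97 ± 0.19) and Aurka (-0.90 ± 0.14) and the cyclin Ccna2 (-1.01 ± 0.15; -0.65 with its probe sets averaged) fell. The median was -0.47 and the camera adjusted p 5.4e-07, with adjusted p = 0.25 with an estimated correlation.

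Genes of DNA methylation and chromatin repression were lower for 8 of 21 members and higher for 1 (8 and 2 adjusted over the list alone). Uhrf1, which guides DNA methylation to newly replicated DNA, fell from 1546 to 642 (-1.26 ± 0.15). The DNA methyltransferase Dnmt3b had a difference of -1.05 ± 0.27 and lost its call without E11.5 replicate 1 (-0.80), without E14.5 replicate 1 (-0.85), without a filter and with probe sets averaged (-0.56). The methyl-binding proteins Mbd4 (-0.63 ± 0.19) and Mbd2 (0.58 ± 0.16) passed the test with all 4 arrays. Mbd4 lost its call when any 1 array was left out, with differences from -0.69 to -0.57. The protein Mbd2 lost its call without E11.5 replicate 1 (0.53), without E14.5 replicate 1 (0.59) and without E14.5 replicate 2 (0.57). Both also lost their calls without the variance trend, with probe sets averaged (-0.50 and 0.19) and under another scaling. The list had a median of -0.23 and a camera adjusted p of 0.016, with adjusted p = 0.26 with an estimated correlation. Without E14.5 replicate 1 the adjusted p was 0.11 for this list of DNA methylation and chromatin repression, and its lowest value under any alternative was 0.0048.

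Signalling pathways linked to glial fate were tested as 5 further lists. In the JAK-STAT pathway, through which cytokines of the leukemia inhibitory factor family induce astrocyte genes, 5 of 17 members were higher and 2 lower, also adjusted over the list alone. Stat3 rose from a mean of 334 to 1941 (2.49 ± 0.13), the receptor subunit Lifr from 144 to 587 (1.93 ± 0.20) and the kinase Jak2 from 533 to 896 (0.74 ± 0.14). The pathway inhibitor Socs2 fell from 359 to 136 (-1.37 ± 0.24; -0.57 with its probe sets averaged). The list as a whole did not shift (median 0.04, adjusted p = 0.27).

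In the BMP-SMAD pathway 4 of 18 members were higher and 2 lower, also adjusted over the list alone. The receptor Bmpr1b rose from 97.7 to 493 (2.19 ± 0.17) and the BMP antagonist Nbl1 by 1.94 ± 0.37, while the antagonist Fst fell from 79.5 to 19.7 (-1.66 ± 0.43). Fst lost its call without the variance trend and without a filter, and its difference was -0.99 without E14.5 replicate 2. The receptor Bmpr2 was called higher at its brightest probe set only (0.66 ± 0.13). Its 2 other probe sets had differences of -0.17 and -0.40 and did not pass, and with the 3 averaged its difference was 0.030 and its call was lost, as it was without the variance trend. The list did not shift (adjusted p = 0.92), and its median of -0.18 had the opposite sign to its mean of 0.04 and to the test.

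Notch pathway genes were higher for 8 of 20 members and lower for 1, also adjusted over the list alone. After Dll3 (693 to 2693) and Hes5, the receptor Notch1 rose from 793 to 2267 (adjusted p = 2.6e-05) and the glycosyltransferase Lfng by 1.13 ± 0.17. The ligand Jag1 fell (-0.89 ± 0.20). The median was 0.25 and the camera adjusted p 0.033, with adjusted p = 0.29 with an estimated correlation and 0.084 without the variance trend. The lowest adjusted p of the Notch pathway under any alternative was 0.0054. Its median was 0.37 without E14.5 replicate 1 and 0.14 without E14.5 replicate 2.

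The Wnt pathway had 4 of 21 members higher and 6 lower, also adjusted over the list alone. The ligand Wnt8b (168 to 12.3; -2.87 ± 0.34), the transcription factor Lef1 (-1.56 ± 0.24) and the receptor Fzd8 (-1.50 ± 0.17) fell, and the receptor Fzd9 rose (1.84 ± 0.17). This list did not shift (adjusted p = 0.61), and its median of 0.13 had the opposite sign to its mean of -0.18 and to the test. In the FGF and ERK pathway 5 of 17 members were lower and 2 higher, also adjusted over the list alone. Besides Fgf15, the ERK phosphatase Dusp4 fell from 1802 to 147 (-3.55 ± 0.24) and Fgf13 by 1.34 on the log2 scale, while the growth factor receptor Egfr rose from 102 to 2650 (4.53 ± 0.14). The FGF and ERK pathway list had a median of -0.26 and a camera adjusted p of 0.041, with adjusted p = 0.29 with an estimated correlation. Its adjusted p was 0.061 without E11.5 replicate 1 (median -0.23) and 0.075 without E11.5 replicate 2 (median -0.39), and it also missed the threshold without the variance trend (0.054) and with the stricter filter (0.076). Its lowest value under any alternative was 0.013.

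**Figure D2:**
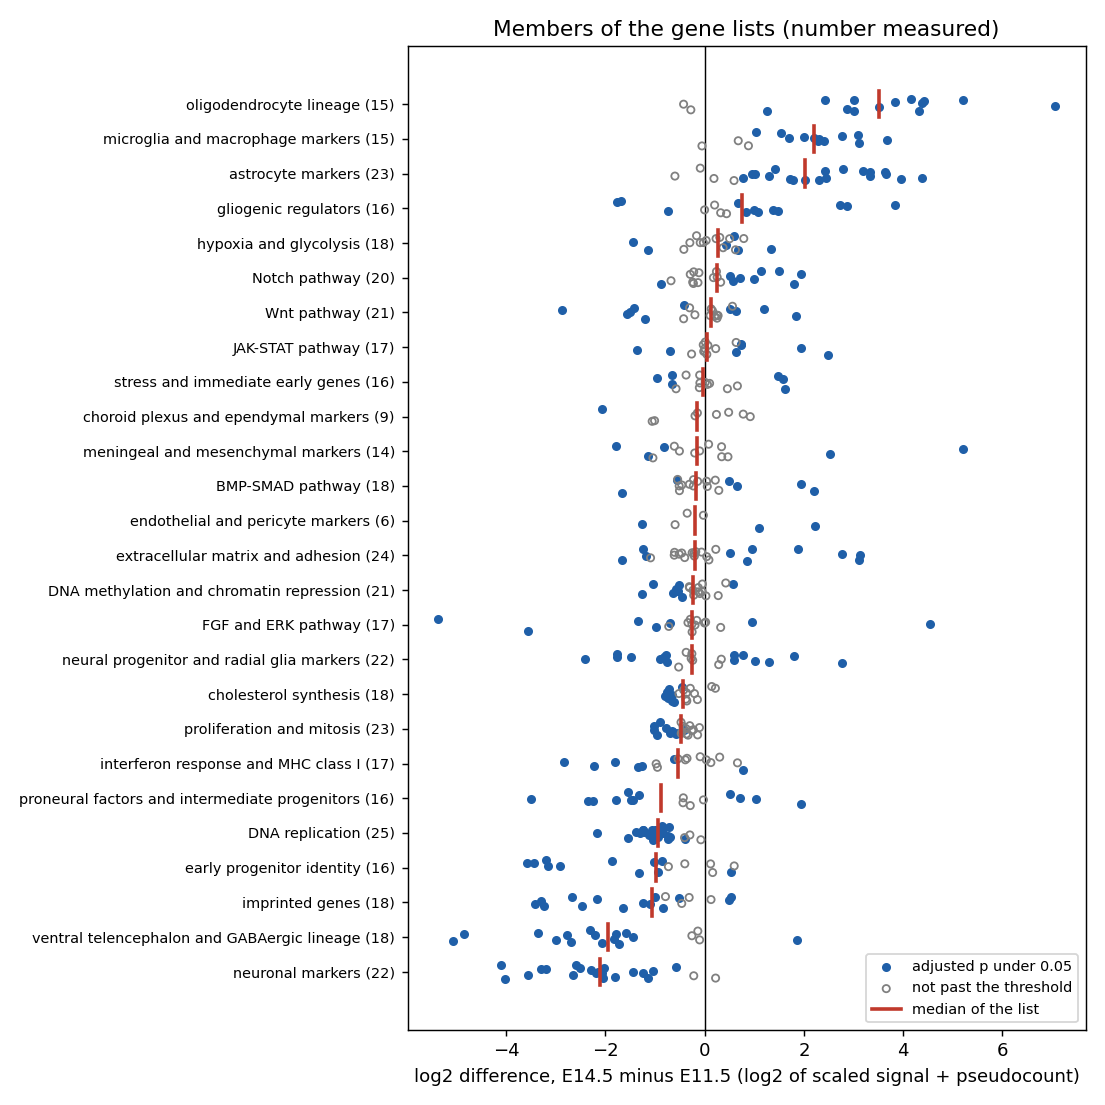
Log2 difference, E14.5 minus E11.5, of each measured member of the 26 tested gene lists, with the number measured in parentheses after the name of each list. Filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians, which run from 3.51 for the oligodendrocyte lineage to -2.11 for neuronal markers.

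Extracellular matrix and adhesion genes did not shift together (adjusted p = 0.63, median -0.19, mean 0.20), with 7 of 24 members higher and 3 lower (7 and 4 adjusted over the list alone). The brain proteoglycans Bcan (642 to 5708; 3.13 ± 0.13), Cspg5 (3.10 ± 0.13) and Ncan (1.87 ± 0.11) rose, as did Tnc. The members that fell were the fibronectin gene Fn1 (-1.66 ± 0.29), the laminin Lama1 (-1.25 ± 0.25) and the proteoglycan Vcan (-1.18 ± 0.13).

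Of the 26 lists tested, 5 were higher, 11 were lower and 10 did not pass with the preset correlation. None of the 16 calls held with an estimated correlation, where both the correlation and the test rest on 2 residual degrees of freedom. Estimates were negative for gliogenic regulators (-0.057), early progenitor identity (-0.034), the FGF and ERK pathway (-0.045) and imprinted genes (-0.037). The estimate for DNA methylation and chromatin repression (0.00029) lay below the preset 0.01. Correlation among members thus does not account for the losses of these lists. In the other called lists, estimates ran from 0.012 (Notch pathway) to 0.71 (interferon response and MHC class I). For them, the effects of correlation and of the few degrees of freedom were not separated. Embryonic age and days in culture changed together in these samples, so each difference is one between E11.5 cells after 1 day and E14.5 cells after 4 days.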

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

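Tests of a smaller share of neurons and of RNA from microglia or macrophages were chosen after the results were seen, as were the look at the control probe sets and the reading of the brightness test for neuronal markers described here; the other tests were planned.

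The arrays carry 4 control probe sets for mouse pyruvate carboxylase, which stand outside the genes tested, and all 4 were higher on both E14.5 arrays than on both E11.5 arrays. The ratios of mean scaled signals, E14.5 over E11.5, were 4.99, 2.82, 3.64 and 5.77, and no test was run on them. The gene itself, Pcx, was tested through another probe set and rose from a mean of 166 to 1051 (log2 difference 2.56 ± 0.18).

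Astrocyte and oligodendrocyte lineage genes were higher at E14.5, with a median log2 difference of 2.61 over the 38 members of both lists, and the E14.5 arrays were also dimmer before scaling. If brightness made the difference, members would differ by 1.69 between the dimmer and the brighter array within a group. Averaged over the 2 groups, they differed by -0.056 (95% bootstrap interval -0.14 to 0.12), which argues against array brightness in these arrays. The bootstrap resampled the members, so this interval covers the spread among genes, not between arrays. The same holds for the intervals given below for neuronal and for microglia and macrophage markers. Days in culture and embryonic age cannot be told apart, because 0 embryonic ages have arrays at more than 1 culture time. Embryonic age therefore stays an untested explanation beside days in culture.

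Neuronal markers were lower at E14.5, with a median of -2.11, where brightness would need a difference of -1.36 within groups. Averaged over the 2 groups, they differed by -0.22 (interval -0.37 to -0.04), 15.8% of that value, which argues against brightness as the whole cause. The average hides a difference between the groups for some members. From the brighter to the dimmer array, Stmn2 went from 231 to 102 and Tubb3 from 236 to 109 at E14.5. At E11.5 they went from 2889 to 2813 and from 1996 to 2094. The groups were not tested separately. The bound set beforehand, -0.34, was not cleared by the interval, and this reading against the full value was adopted after the result was seen, so a contribution of brightness stays open. Pan-neuronal, glutamatergic and GABAergic marker subsets had medians of -2.15, -2.08 and -2.49, so the highest was -2.08. These subsets hold markers already seen to fall, so the test gives no support to a smaller share of neurons in the E14.5 cultures and does not exclude it. Loss of neurons in longer culture, age, and lower expression per neuron stay open and were not separated.

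Microglia and macrophage markers were higher at E14.5 with a median of 2.20, where brightness would need 1.42 within groups. Averaged over the 2 groups, the members differed by -0.26 (interval -0.32 to -0.15), which argues against brightness. Of the 15 measured members, 80% were called higher, and Cx3cr1, Spi1 and Trem2 did not pass the test. That share was known before it was taken as a test, so it gives no support to RNA from microglia or macrophages in the cultures and does not exclude it. No sort that would remove such cells is named in the labels. Whether such cells were present, and whether they came with the tissue at E14.5 or grew over 4 days, stays open.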

How the results depend on the processing

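The alternatives compared in this part were planned before the results were seen. The arrays differ in brightness and their number limits what can be called. Of 1578 comparisons of the 114 called genes named by rule with the alternatives that tested them, 1534 kept direction and call, 44 lost the call and 0 reversed. Of these genes, 100 kept their call under every alternative tested. They were picked for large differences in these same data, so this does not describe all calls. With all 4 arrays, the share of all called probe sets that were kept ran from 60.1% without the variance trend and 70.6% without a filter to 99.97% with the larger pseudocount. Of 164 comparisons of the 12 genes named by rule without a call, 14 passed and 11 reversed. Without the variance trend, 1919 probe sets were higher and 2097 lower, with 1150 and 1101 genes; 60.1% of the calls were kept, and the cause was not tested. With an estimated correlation, 0 lists were higher and 0 lower. The adjusted p was then 0.2465 for astrocyte markers, gliogenic regulators, early progenitor identity, neuronal markers, ventral telencephalon and GABAergic lineage, oligodendrocyte lineage, proliferation and mitosis, and microglia and macrophage markers, and 0.2932 for DNA replication. Both that correlation and the test that uses it rest on 2 residual degrees of freedom. With this alternative set aside, 12 of the 16 called lists kept their call under every alternative. The adjusted p over the other alternatives reached 0.084 for the Notch pathway, 0.11 for DNA methylation and chromatin repression, 0.076 for the FGF and ERK pathway and 0.35 for interferon response and MHC class I, from lowest values of 0.0054, 0.0048, 0.013 and 6.1e-06.

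The number of probe sets 2-fold apart between replicates, for E11.5 and E14.5, was 1303 and 1895 with a pseudocount of an eighth, 124 and 167 with the median as pseudocount, 1935 and 3548 without a filter, and 201 and 188 with the filter at the 60th percentile. A larger pseudocount shrinks low signals and a stricter filter leaves fewer probe sets. Leaving out 1 array at a time left 2256 to 3148 probe sets higher and 2750 to 3405 lower. Median scaling moved the median of all probe sets to -0.05.

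The direction turned for values that had not passed the test, and the cause was not tested. For the BMP-SMAD pathway the adjusted p was 0.878 without a filter, 0.923 without the variance trend and 0.753 with probe sets averaged. It was 0.622 for endothelial and pericyte markers without a filter and 0.999 for stress and immediate early genes without the variance trend. With 1 array left out, the adjusted p ran from 0.482 to 0.946 for meningeal and mesenchymal markers, which turned in 3 of 4 cases, and from 0.900 to 0.955 for stress and immediate early genes, which turned in 1. With 1 array left out, log2 differences ran across 0 for Clu (-0.39 to 0.77), Slc7a10 (-0.60 to 0.43), Nr2f1 (-0.024 to 0.26), Prtg (-0.83 to 0.031) and Pou3f2 (-0.24 to 0.24). Pou3f2 also turned under quantile normalization (0.057) and with the median as pseudocount (0.0019).

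The labels do not say that the replicate numbers pair the arrays. The differences of replicate 1 minus replicate 2 correlated across probe sets at 0.0041 between the groups. So low a correlation between single differences does not exclude pairing. With the replicate block 7173 probe sets were called, against 6408 without it. With it Gja1, Cd44, Dmrta1 and Crabp1 passed; among the 126 genes named by rule it changed no other call, and it changed that of no list. Genes named outside the rule were not compared.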

Other observations

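The look at control transcripts was chosen after the results were seen, and the list tests were planned. Imprinted genes fell as a group, with 12 of 18 measured members lower and 2 higher (13 and 2 adjusted over the list alone). The noncoding RNAs Meg3 (1312 to 113; -3.42 ± 0.19) and Rian (-3.24 ± 0.18), the delta-like protein Dlk1 (-3.30 ± 0.27) and Usp29 (-2.66 ± 0.38) fell most (with probe sets averaged Meg3 had -2.18, Rian -2.06 and Usp29 -1.69), while Gnas (0.50 ± 0.12) and Impact (0.54 ± 0.17) rose. The median was -1.05 and the camera adjusted p 3.1e-07, with adjusted p = 0.25 with an estimated correlation. Genes of cholesterol synthesis were lower for 8 of 18 members and higher for none (9 and none adjusted over the list alone). The enzymes Lss (-0.79 ± 0.16), Fdft1 (-0.75 ± 0.13), Sc5d (-0.74 ± 0.16) and Cyp51 (-0.73 ± 0.16) fell most. Lss lost its call without the variance trend, and Cyp51 lost its call there and without E14.5 replicate 2, where its difference was -0.51. The median of cholesterol synthesis was -0.44 and the camera adjusted p 0.00039, with adjusted p = 0.45 with an estimated correlation.

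Interferon response and MHC class I genes were lower for 6 of 17 members and higher for 1, Irf1 (7 and 1 adjusted over the list alone). Usp18 (-2.84 ± 0.32), Bst2 (-2.22 ± 0.34), Ifitm3 (-1.80 ± 0.29) and Irf9 (-1.35 ± 0.22) fell most. On the E11.5 arrays Usp18 stood at 509 and 235 and Bst2 at 312 and 136. The list of interferon response and MHC class I had a median of -0.54 and a camera adjusted p of 0.018, with adjusted p = 0.73 with an estimated correlation. Without E11.5 replicate 1 the median was -0.055 and the adjusted p 0.35, so the size of the shift depends on that array. Without E11.5 replicate 2 the median was -0.9985. Over all alternatives the adjusted p ran from 6.1e-06 to 0.73. Hypoxia and glycolysis genes did not shift (median 0.27, adjusted p = 0.59), with 4 of 18 members higher and 2 lower (6 and 3 adjusted over the list alone). Hexokinase Hk2 (-1.44 ± 0.18) and the glucose transporter Slc2a1 (-1.14 ± 0.26) fell, and Egln3 (1.34 ± 0.24) and Ldha (0.67 ± 0.13) rose; Slc2a1 and Ldha lost their calls without the variance trend, and Slc2a1 had a difference of -0.75 without E14.5 replicate 2. Stress and immediate early genes did not shift either (median -0.04, mean 0.15, adjusted p = 0.90), with 3 of 16 members higher and 3 lower, also adjusted over the list alone. Hmox1 (1.63 ± 0.24), Fos (1.59 ± 0.21) and Atf3 (1.48 ± 0.37) rose and Ier2 fell (-0.96 ± 0.19), and the call of Atf3 was lost without E11.5 replicate 2 (1.12) and without a filter. Of the sex-linked transcripts 4 were measured, too few for the list test, and none passed, over all probe sets or adjusted over the list alone.

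Control probe sets for the mouse transferrin receptor were lower at E14.5, by 3.51 to 9.14 times for the 3 probe sets, and the gene itself, Tfrc, fell from 1526 to 629 (-1.26 ± 0.13). The arrays also carry 27 probe sets for Bacillus subtilis transcripts, which mouse cells do not make and which are commonly added to RNA as controls. After scaling, all 27 were higher on both E14.5 arrays than on both E11.5 arrays, with a median log2 difference of 0.85 (0.48 to 1.30). The 18 probe sets for bioB, bioC, bioD and cre, which are commonly added to the hybridisation mix, had a median of 0.24 (-0.04 to 0.43). Scaled signals reached 10478 for the Bacillus subtilis probe sets and 9107 for the others, so such controls were present. In what amount and at which step they were added is not given in the sources used here. Of the 1850 genes called higher, 1038 had a log2 difference above 0.85. The medians of gliogenic regulators (0.75) and of the Notch pathway (0.25) lay below that value, and those of astrocyte markers (2.02), microglia and macrophage markers (2.20) and the oligodendrocyte lineage (3.51) above it. Directions in all comparisons are thus relative to the average signal of an array, and scaling to these controls was not run.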
